A study of Mus musculus with 8 samples.

How the data were processed

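H2A.Z, a histone H2A variant, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole testis cells of mice at postnatal day 14. The 8 libraries fall into 4 groups of 2 replicates: H2A.Z immunoprecipitates and inputs of control testes, and the same for testes labelled Znhit1-CKO (Znhit1-sKO in the labels' protocol). The protocol names 2 independent biological replicates and over 30000000 reads per library. Depth per library cannot be read from the files, which hold no read counts.

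Per the submitters' processing notes, the tools named were cutadapt 2.5, BWA 0.7.17, SAMtools 1.9, Picard 2.20.7 and MACS2 2.2.4, and the genome build was mm10. The authors deposited 3 lists of regions: the control peaks, the Znhit1-CKO peaks and a list of differential regions between them, which its own name credits to edgeR. Each list gives a chromosome, a start and an end and nothing else. The peak threshold, any pooling of replicates, the threshold for a differential region, and its direction are not given in the sources used here. A peak list with 1 entry per genotype has no replicate error, so no difference between the 2 peak lists was tested against the spread between animals. Intervals and tests over peaks or genes describe these lists and cover counting error only, and neighbouring peaks and genes are not independent. A peak is a region that passed a threshold, so a site can leave a list because its signal fell, because background rose or because fewer reads were sequenced.

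Peaks were taken as shared where they overlapped by at least 1 bp. Genes came from the RefSeq table of GRCm38.p6, whose primary coordinates are those of mm10. That table holds 49997 genes, 21900 of them protein-coding, with start and end but no strand. A gene boundary peak was therefore any peak within 1000 bp of either end of a protein-coding gene, where a window around the transcription start had been planned. Of 13961 genes longer than 10000 bp, 71.1% had a control peak at 1 end and 6.18% at both ends. Start coordinates in the text count from 1.

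Several other planned steps changed with the files. Peak strength was replaced by peak width, since no fold or p accompanies a peak. Differential regions carry no sign, so control peaks with a differential region were compared with control peaks without one, and the gene list outcome was the planned substitute, a gene with a control boundary peak and no Znhit1-CKO boundary peak (called lost below). CpG content was not analysed here, because no sequence was used.

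Shares carry exact (Clopper-Pearson) 95% intervals. Odds ratios carry Woolf intervals with two-sided Fisher's exact tests, or come from logistic regression where width or position is a covariate. Medians were compared by two-sided permutation tests with 100000 resamples, in which 1e-05 is the smallest p possible. Chance overlap came from 100 circular shifts of the Znhit1-CKO peaks along each chromosome. Paired widths were compared for control and Znhit1-CKO peaks that overlapped one another and no other peak, as log2 of Znhit1-CKO over control width. The 13 gene lists (12 by name and the olfactory receptors by symbol) were fixed before the data were examined, as were their tests and those of peak position, chromosome and strength. The shifts, the paired widths, width as a covariate and the width-matched lists were added after the files were seen. They were tested by Fisher's exact test with Benjamini-Hochberg adjustment over the 13 lists, against all other protein-coding genes with a control boundary peak. Of the 467 members of the 12 lists, 9 are in more than 1 list. H1f9 alone was not found in the table. A list was also compared with 10000 random lists of the same size, drawn to match the width of the control boundary peak. This upper-tail resampling test asked only for more losses, not fewer.

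Genes were named by a rule written beforehand: the 10 lost genes with the widest control boundary peak (width standing in for the planned fold), leaving out predicted genes, up to 4 members per list with a differential region at a boundary, in order of symbol since no p is given, and Znhit1, H2az1 and H2az2. Other genes are said to have been chosen after their values were seen. Overlap counts were checked against bedtools 2.31.1, with 0 differing counts among 48752 control peaks. On simulated loss at gene boundaries, 96 of 100 intervals held the simulated odds ratio. For gene lists with simulated loss raised from 10% to 30%, 93.5% of 200 lists were called, and 1% of 200 unchanged lists. The simulated lists held independent genes and were larger than most real ones, which had as few as 13 genes with a control boundary peak. The 93.5% does not hold for such small lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

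Alternatives planned beforehand were an overlap of at least 50% of both peaks, a gap of up to 500 bp, and windows of 500 bp and 2000 bp at gene boundaries. Those that need a fold, p, q or FDR could not be run. Alternatives added after seeing the data were a minimum width of 500 bp, the widest control peaks, covered length, width as a covariate, all annotated genes, gene-boundary or other peaks alone, and other outcomes for the gene lists. The analysis was run in full more than once, and 3 tests of explanations were replaced or extended after their first values were seen. Both forms of each are given with the other observations.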

Results

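The series asks how ZNHIT1, a subunit of the SRCAP complex that exchanges H2A for H2A.Z, affects where H2A.Z lies in the genome of male germ cells. It compares testes of control and Znhit1-CKO (conditional knockout) mice at postnatal day 14. H2A.Z immunoprecipitates and inputs were sequenced from 2 replicates per genotype. What is compared here is 1 peak list per genotype and 1 list of differential regions, so the values carry no replicate error.

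Fewer H2A.Z peaks were called in Znhit1-CKO testes. The control list held 48752 peaks covering 43.5 Mb, and the Znhit1-CKO list 31156 peaks covering 25.2 Mb, which is 63.9% of the number and 58.0% of the length. Znhit1-CKO peaks were also narrower, with a median width of 667 bp against 742 bp. Of the control peaks, 24020 (49.3%, 95% interval 48.8 to 49.7%) overlapped a Znhit1-CKO peak, against 2.05% ± 0.077 (SD over 100 shifts) for shifted peaks. Of the Znhit1-CKO peaks, 5568 (17.9%, 17.4 to 18.3%) had no control peak. They were narrow, with a median of 345 bp against 795 bp for the other Znhit1-CKO peaks. Whether the lists differ by more than 2 replicates do was not testable, and the share of control peaks called again depends on the overlap required. So does the share of Znhit1-CKO peaks without a control peak, 39.2% where 50% of both peaks had to overlap. It was 5.66% for Znhit1-CKO peaks of at least 500 bp.

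Peaks next to genes were called again far more often than peaks elsewhere. Within 1 kb of the end of a protein-coding gene, 12424 of 15147 control peaks (82.0%, 81.4 to 82.6%) had a Znhit1-CKO peak. Elsewhere 11596 of 33605 did (34.5%, 34.0 to 35.0%). Gene boundary peaks therefore made up 31.1% of the control list and 43.6% of the Znhit1-CKO list. The odds ratio for loss at boundaries against elsewhere was 0.115 (0.110 to 0.121), and 0.201 with the boundaries of all annotated genes. Lost control peaks had a median width of 516 bp and shared ones of 1175 bp (permutation test, p = 1e-05, the smallest the test can give). With log2 width as a covariate the odds ratio was 0.285 (0.269 to 0.301). Among the narrowest of 4 width groups the odds ratio was 0.851 (0.728 to 0.996), and among the widest 0.0911 (0.0780 to 0.106). The gene ends carry no strand, so start and end of transcription are not separated.

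**Figure D1:**
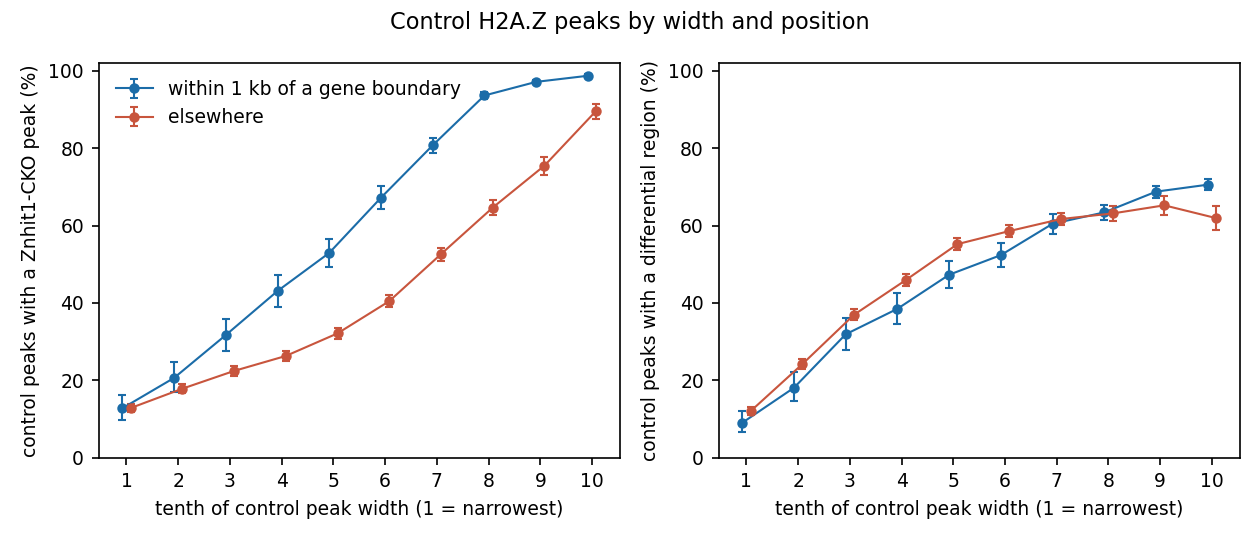
Percentage of control H2A.Z peaks that overlap a Znhit1-CKO peak (left) or a differential region (right), in 10 equal groups of control peak width, for peaks within 1 kb of a gene boundary (blue) and elsewhere (red); bars are exact 95% binomial intervals. In the widest group 98.7% of boundary peaks and 89.6% of the others overlap a Znhit1-CKO peak, and in the narrowest 12.8% and 12.9%.

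The authors' differential regions lay almost wholly on control peaks. Of 24367 regions, 12747 (52.3%) overlapped only control peaks, 11023 (45.2%) peaks of both lists, 385 (1.58%) only Znhit1-CKO peaks and 212 (0.870%) neither. Of the regions over 1 list only, 97.1% (96.8 to 97.4%) were over control peaks. An even split is not the reference, since 24732 control peaks and 5568 Znhit1-CKO peaks were in 1 list only. A region lay on 51.2% of the former and on 6.91% of the latter, which were narrow (median 345 bp). The list gives no sign, so a region over a peak of both lists has no stated direction. Among 22040 pairs of overlapping peaks, the Znhit1-CKO peak was the narrower in 78.6%, with a median log2 width ratio of -0.27. At the 10120 pairs with a differential region the median was -0.33, and at the other 11920 it was -0.21 (permutation test, difference -0.12, p = 1e-05, the smallest possible). A pair was classed by its control peak, and wide control peaks more often had a region, so part of this difference is built in. Control peaks at gene boundaries more often had a differential region, 59.6% (58.9 to 60.4%) against 44.0% (43.5 to 44.6%) elsewhere, an odds ratio of 1.88 (1.81 to 1.95). With log2 width as a covariate that direction turned, to 0.805 (0.768 to 0.844). Lost control peaks had a differential region at 51.2% and shared ones at 46.5%. At gene boundaries it was 53.1% of lost and 61.1% of shared peaks, and elsewhere 51.0% and 30.8%. A lost call therefore does not by itself mean a differential site.

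The X chromosome, which is silenced in pachytene spermatocytes, differed from the autosomes. Of its 782 control peaks, 30.4% had a differential region, against 49.2% on the autosomes, an odds ratio of 0.452 (0.388 to 0.527, Fisher's exact test, p = 5.59e-26). It was 0.453 (0.385 to 0.532) with boundary position and log2 width as covariates. Among the narrowest of 4 width groups no difference was detectable (0.924, 0.640 to 1.33). Over all peaks fewer X peaks were lost (odds ratio 0.616, 0.533 to 0.712), as they were away from gene boundaries (0.561, 0.446 to 0.705) and with boundary position and log2 width as covariates (0.770, 0.646 to 0.919). At gene boundaries without a covariate more were lost, 31.3% against 17.5% (2.14, 1.76 to 2.61). With log2 width as a covariate the boundary value was 0.852 (0.660 to 1.10), an interval that includes 1. Of 464 X genes with a control boundary peak, 26.5% had lost it, against 11.1% of autosomal genes. These gene shares are not adjusted for peak width. The Y chromosome had 6 control and 8 Znhit1-CKO peaks, too few to compare.

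**Figure D2:**
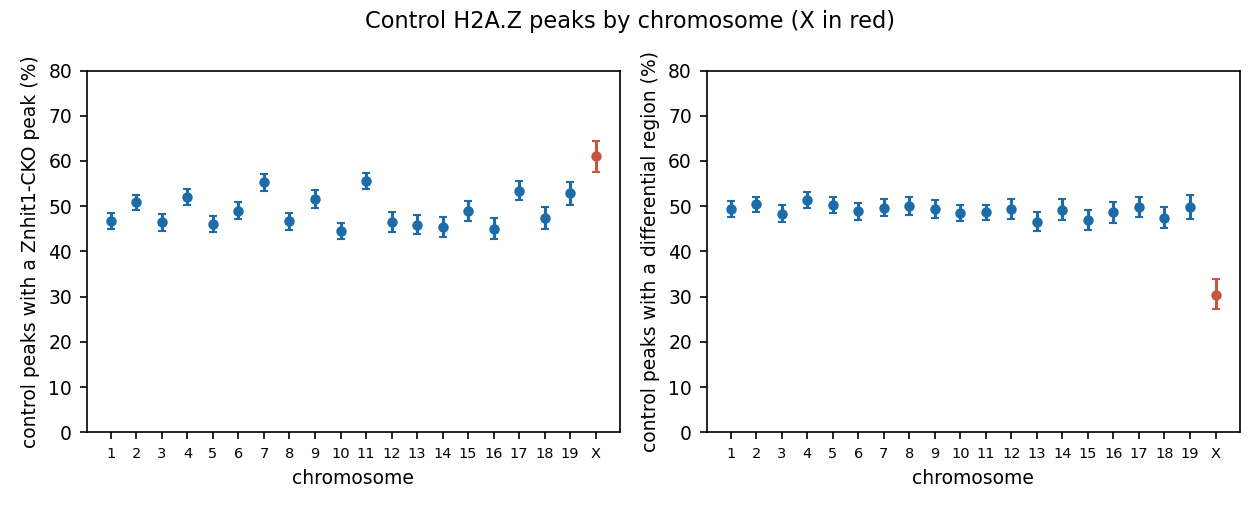
Percentage of control H2A.Z peaks on each autosome (blue) and the X (red) that overlap a Znhit1-CKO peak (left) or a differential region (right); bars are exact 95% binomial intervals. The X has 61.0% with a Znhit1-CKO peak and 30.4% with a differential region.

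Of 21900 protein-coding genes, 14815 had a control boundary peak and 13227 a Znhit1-CKO one. The peak was kept at 13104 genes and lost at 1711 (11.5% of 14815, 11.0 to 12.1%), while 123 genes had only a Znhit1-CKO peak, 5 of them with a differential region. A differential region lay at 9309 of the 14815 (62.8%), at 63.4% of the kept genes and 58.6% of the lost ones. Znhit1 itself kept a boundary peak, 2003 bp wide in control (chromosome 5, 136986268 to 136988270) and 1422 bp in Znhit1-CKO. H2az1 and H2az2, which encode H2A.Z, kept theirs as well, and all 3 genes had a differential region. A gene counted as kept where any Znhit1-CKO peak lay at a boundary, whatever its width. The H2az1 control peak of 2277 bp overlapped 3 Znhit1-CKO peaks of at most 669 bp. That of H2az2, 1518 bp wide, overlapped 2 of at most 778 bp. A peak at Znhit1 says nothing of whether the gene was deleted.

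The 10 lost genes with the widest control peak were Pcdh8 (3613 bp), Sox21 (3071 bp), Nanos2 (2924 bp), Tyro3, Plxnb1, Ngfr, Ccdc85c, Chat, Slc18a3 and Mapt. They include a protocadherin gene, a SOX transcription factor gene, and Nanos2, which maintains spermatogonial stem cells. At Pcdh8 the peak on chromosome 14 (79768191 to 79771803) overlapped no Znhit1-CKO peak and had a differential region. The same absence of overlap held for Ngfr, and for Chat and Slc18a3, which share 1 peak. At the other genes a Znhit1-CKO peak overlapped the control peak but lay more than 1 kb from the gene boundary. Counting a gene as lost only where no Znhit1-CKO peak overlapped its control peak gave 1594 genes (10.8%).

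Germ cell genes lost boundary peaks more often than other genes. Of the genes of the meiotic chromosome axis, synapsis and recombination, 15 of 52 with a control boundary peak had lost it (28.8%, 17.1 to 43.1%), against 11.5% of other genes (odds ratio 3.12, 1.71 to 5.70, Fisher's exact test, adjusted p = 0.00124). Chosen after their values were seen, these include Sycp1, Sycp2 and Sycp3, which build the synaptonemal complex, the protein axis between paired homologues. Their control peaks were 1037, 1099 and 944 bp wide, none overlapped a Znhit1-CKO peak, and each had a differential region. Ankrd31, which acts with the machinery for meiotic double-strand breaks, and Ccnb1ip1, which is needed for crossovers, were lost too. The naming rule admits only list members with a differential region, which both therefore had. The genes 4930432K21Rik (Brme1) and Bhmg1 (Meiosin), named by the same rule, kept a peak. It was 1343 bp wide in control and 1433 bp in Znhit1-CKO at the first, and 1200 bp and at most 464 bp at the second. Spo11, the gene of the enzyme that makes the breaks, was also chosen after its values were seen. It lost a narrow peak of 409 bp with no differential region. In all, 11 of the 15 had a differential region, against 58.6% of all lost genes.

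Genes of pachytene spermatocytes lost 14 of 43 peaks (32.6%, 19.1 to 48.5%; odds ratio 3.72, adjusted p = 0.000563), among them Brdt, a testis bromodomain gene (1041 bp), and Adam3 (905 bp), while Catsper2 and Cdc25c kept theirs. Spermiogenesis genes lost 8 of 25 (32.0%, 14.9 to 53.5%; odds ratio 3.62, adjusted p = 0.0103), among them Acrbp, Actl7b and Crisp2. Each of the 8 had a differential region, and Cabyr kept its peak. With log2 width as a covariate the spermiogenesis odds ratio was 3.72 (1.39 to 9.95, adjusted p = 0.0194), but the call ended against width-matched random lists, which lost 4.12 on average (upper-tail resampling test, adjusted p = 0.050). At Izumo1, chosen after its values were seen, a Znhit1-CKO peak still overlapped the control peak. Genes of the piRNA pathway, which silences transposons in germ cells, lost 12 of 27 (44.4%, 25.5 to 64.7%; odds ratio 6.16, adjusted p = 7.71e-05), including Asz1 (983 bp) and Btbd18 (878 bp), with Ddx4 and Ddx39a kept. The piRNA control peaks were narrow (median 878 bp). Their odds ratio was 3.19 (1.23 to 8.31, adjusted p = 0.0322) with log2 width as a covariate, and the call ended against width-matched random lists, which lost 7.91 on average (upper-tail resampling test, adjusted p = 0.0622). Spermatogonial genes lost 12 of 33 (36.4%, 20.4 to 54.9%; odds ratio 4.40, adjusted p = 0.000563), including Crabp1 (2212 bp), while Cd9, Dnmt3b and Eomes kept theirs. The spermatogonial call ended with a 2 kb window (odds ratio 2.49, adjusted p = 0.0769) and where a differential region was also required (2.47, adjusted p = 0.112), as 5 of the 12 had. With log2 width as a covariate the odds ratio was 10.5 (3.96 to 28.1, adjusted p = 1.04e-05). That value counts as lost some wide control peaks that a Znhit1-CKO peak still overlapped, such as that of Nanos2. Where no such overlap was allowed, 9 of 33 were lost (odds ratio 3.12, 1.45 to 6.73, adjusted p = 0.0144 by Fisher's exact test).

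Loss was not confined to the lists named for germ cell genes. No expression data were used, so whether the lost genes of other lists are active in germ cells was not tested. Developmental transcription factors, Polycomb targets in embryonic cells, lost 22 of 49 peaks (44.9%, 30.7 to 59.8%; odds ratio 6.31, adjusted p = 3.02e-08). Dlx2, Fgf8, Foxa2 and Foxd3, named by the rule that requires a differential region, kept a peak. Their control peaks of 1901, 1432, 1802 and 2124 bp overlapped Znhit1-CKO peaks of at most 702, 269, 435 and 487 bp. Olfactory receptor genes, of which 50 of 1110 had a control boundary peak, lost 46 (92.0%, 80.8 to 97.8%; odds ratio 90.5, adjusted p = 8.23e-38), Olfr1342 and Olfr1344 among them. Their odds ratio was 31.6 with log2 width as a covariate (logistic regression, adjusted p = 7.62e-09). It was 23.2 where a differential region was also required, an outcome that carries over the excess of loss. With a differential region alone as the outcome it was 1.15, at 66.0% of these genes against 62.8% of others. Markers of Sertoli cells lost 4 of 19 (adjusted p = 0.288), Cldn11 and Clu included, and those of Leydig, peritubular, endothelial and immune cells 4 of 13 (adjusted p = 0.0779), Cnn1 included. Neither passed the test, and both intervals are wide (6.05 to 45.6% and 9.09 to 61.4%).

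The other 4 lists showed few losses. None of 29 G2/M cell cycle genes (upper limit 11.9%, adjusted p = 0.0695) and none of 25 genes of H2A.Z and its exchange complexes (upper limit 13.7%, adjusted p = 0.127) lost a boundary peak, with Aurka, Aurkb, Actl6a and Anp32e kept. Meiotic silencing and DNA damage genes lost 1 of 24 (adjusted p = 0.515), with Atm, Atr and Brca1 kept, and cytoplasmic ribosomal protein genes 2 of 53 (adjusted p = 0.109). None of the 4 lists passed the test. Width-matched random lists lost few too, on average 1.86 genes for the G2/M list, 1.33 for the H2A.Z list and 2.24 for the silencing list. For the ribosomal protein list they lost 6.15. With a differential region as the outcome, none of the 13 lists passed Fisher's exact test (adjusted p from 0.242 to 1), and 1 had an unadjusted p under 0.05, the spermatogonial genes at 42.4% against 62.9% (p = 0.0186).

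**Figure D3:**
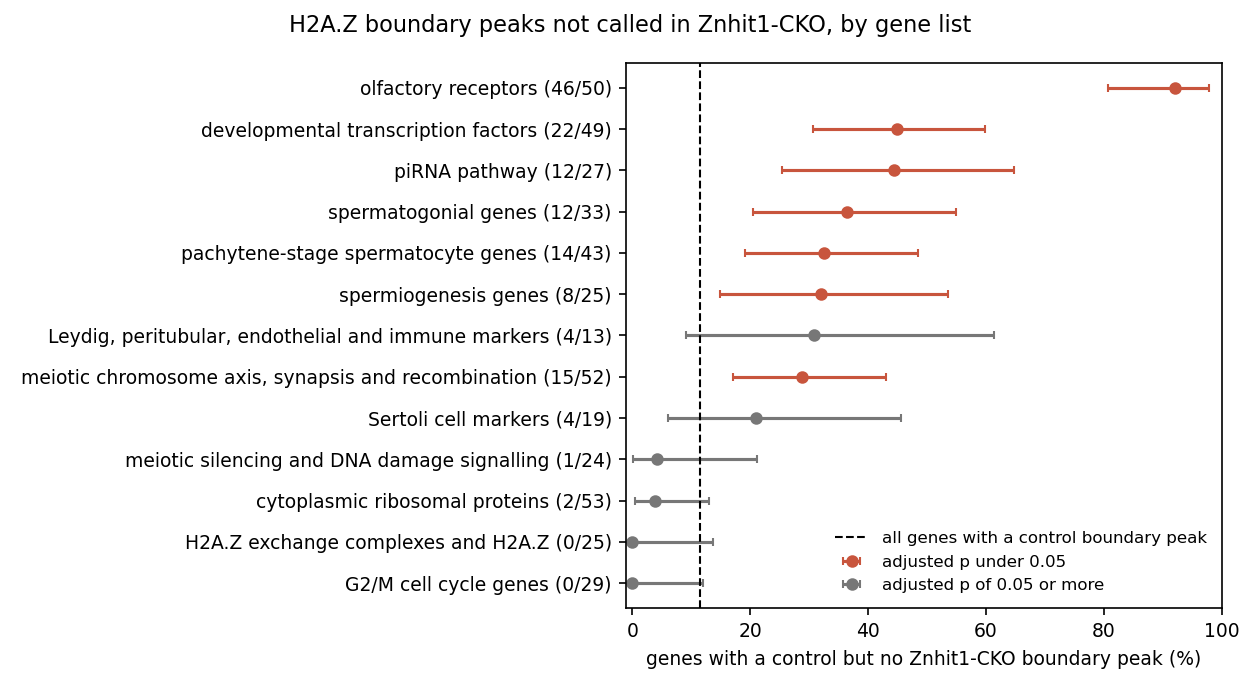
Percentage of genes with a control boundary peak that had no Znhit1-CKO boundary peak, for each of the 13 gene lists, with lost and tested genes in brackets; bars are exact 95% binomial intervals and the dashed line is the 11.5% of all such genes. The 7 lists in red passed Fisher's exact test after adjustment.

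In control testes, boundary peaks were already uneven over the lists. They were present at 52 of 54 meiotic genes (96.3%), 53 of 54 ribosomal protein genes (98.1%) and 29 of 30 G2/M genes (96.7%), against about 67.6% of other genes (adjusted p = 2.07e-06, 1.90e-07 and 0.000792 by Fisher's exact test). Spermiogenesis genes had one less often, at 25 of 53 (47.2%, adjusted p = 0.00615), and olfactory receptor genes at 4.50%. In all, 10 of the 13 lists differed from other genes. Those that did not were the pachytene list (adjusted p = 0.168) and both lists of somatic markers (0.677 and 0.0717).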

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

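The alternatives of minimum width, widest peaks, covered length, width as a covariate, peak position alone and other outcomes were chosen after seeing the data. No paired analysis was possible because the lists hold 1 entry per genotype and no value per replicate, and leaving out a replicate was impossible for the same reason. Alternatives on fold, p, q or FDR and on CpG content were not run. Znhit1-CKO peaks numbered 63.9% of control peaks, 58.6% among peaks of at least 500 bp and 58.0% by covered length. The share of control peaks with a Znhit1-CKO peak (49.3%) was 38.9% where 50% of both peaks had to overlap, 51.5% with a 500 bp gap, 65.9% for the widest control peaks and 62.3% for those of at least 500 bp. The share of Znhit1-CKO peaks without a control peak (17.9%) was 39.2%, 16.3% and 5.66% under the 50% overlap, the gap and the 500 bp minimum. The odds ratio for loss on the X (0.616) was 2.14 at gene boundaries, and 0.852 there with log2 width. That for a differential region at gene boundaries (1.88) reversed to 0.805 with log2 width. The cause was not tested. The count of 7 gene lists fell to 0 with a differential region as the outcome. Of 91 odds ratios for single lists, 76 kept direction and side of the threshold. The 5 that reversed had that outcome: spermatogonial (0.435), pachytene (0.904), H2A.Z complex (1.26), somatic other than Sertoli (0.369) and ribosomal protein genes (1.82). Of 7 calls that ended without reversing, 5 had it too and 2 are the spermatogonial ones in the report. Ribosomal protein genes passed in 3, for less loss (adjusted p 0.0332 to 0.0434). The calls that ended against width-matched lists are not in this count. Depth per library is unknown, so peaks near the threshold are the least certain.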

Other observations

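Most tests here were chosen after results were seen: those on gene families, histone genes, other kinds of gene and loss at boundaries within width groups, both on spermatocyte number, the width change of X pairs, the X odds ratio in the narrowest width group, and the 10 groups of pair width. Width and position as covariates for the X were added after seeing the files.

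Outside the fixed lists, loss of boundary peaks varied with the kind of gene. Among 71 symbol families with at least 20 genes that had a control boundary peak, the only families tested, serine protease genes named Prss lost 12 of 20 (60.0%, adjusted p = 8.44e-06 by Fisher's exact test), Gpr receptor genes 20 of 51 (39.2%, adjusted p = 8.44e-06) and Trim genes 14 of 52 (26.9%, adjusted p = 0.0256). Zinc finger genes named Zfp lost 14 of 341 (4.11%, adjusted p = 3.22e-05). With the olfactory receptors, these were 4 families with more loss and 1 with less. These family shares are not adjusted for width. Median control peak widths were 1073 bp for Prss, 1205 bp for Gpr, 1316.5 bp for Trim and 1435 bp for Zfp genes. Over all protein-coding genes they were 714 bp at lost and 1487 bp at kept genes. Replication-dependent and linker histone genes lost 6 of 58, about as often as other genes (10.3% against 11.6%), yet only 14 of 58 had a differential region (24.1%, 13.9 to 37.2%), against 63.0% of other genes, an odds ratio of 0.187 (0.102 to 0.341) and 0.202 with log2 width. Histone genes lie in clusters and have near-identical copies, so reads shared between copies were not excluded.

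Among genes that are not protein-coding, loss was more frequent than the 11.5% of protein-coding genes. It was 50.7% of 2700 lncRNA genes, 45.0% of 100 miRNA genes, 59.1% of 44 snoRNA genes, 21.1% of 175 tRNA genes and 81.5% of 1166 pseudogenes with a control boundary peak. No width or position adjustment was run for these classes. Control peaks away from protein-coding gene boundaries were lost at 65.5%, above the share in each of these classes but pseudogenes.

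Away from gene boundaries peaks were lost more often in 4 of 4 width groups, so peak width does not account for the whole difference. In the narrowest group the odds ratio for loss at boundaries was only just below 1 (0.851, 0.728 to 0.996). Width is not signal, so weaker peaks of the same width falling below the threshold were not excluded. Whether differential regions at peaks of both lists are mostly sites with more H2A.Z in the knockout was tested by pair width. Such a majority was predicted to leave Znhit1-CKO peaks relatively wider there. The median log2 width ratio was lower, by -0.12 as first tested, a value that mixes pairs of unlike width (median control width 1375 bp at differential pairs and 853 bp at others). In a test added after that value was seen, it was lower with permutation p under 0.05 in 8 of 10 groups of mean pair width, just the number required. The difference ran from -1.01 to -0.08 in the 7 groups of narrower pairs and was -0.01, -0.02 and -0.03 in the 3 of widest pairs (permutation p = 0.825, 0.215 and 0.0236). A pair counted as differential where its control peak overlapped a region. Wide control peaks did so more often, at boundaries 70.6% in the widest of 10 width groups and 9.05% in the narrowest. At a given mean pair width this favours pairs of a wide control and a narrow Znhit1-CKO peak. A lower ratio is thus partly built in, so these medians do not decide whether most such sites gained H2A.Z. They also say little of the widest pairs.

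For the loss of boundary peaks in the 5 germ cell lists, narrow control peaks near the threshold are a technical explanation. All 5 lists lay above 95% of 10000 width-matched random lists, which argues against narrow width as the whole cause. After adjustment of these permutation values over the 13 lists, spermiogenesis and piRNA genes, at permutation p = 0.050 and 0.0622, did not pass. Width is not signal, so weaker peaks of the same width falling below the threshold were not excluded. With a differential region as the outcome, none of these lists passed Fisher's exact test after adjustment. Their odds ratios then ran from 0.435 (spermatogonial) to 1.87 (spermiogenesis). Fewer spermatocytes in the knockout testis may also give more frequent loss of boundary peaks in these lists. As first written, that explanation was to be excluded if 2 or more lists of genes of other cells lost peaks too, and 3 of 5 did, the spermatogonial, developmental and olfactory lists. That bound was set aside after its value was seen, because a list is named for where its genes are expressed and not for which cells carry H2A.Z there. In a test put in its place 0 of 2 somatic lists passed, but the same objection holds for it, so neither test decides. The peaks come from whole testis cells with nothing to assign them to a cell type, which keeps the explanation open.

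X peaks were less often differential, and position and width do not account for it, since the odds ratio with both as covariates was 0.453. Lower power from fewer reads on a single-copy X was to be excluded if the widest X peaks also fell short. They did, with an odds ratio of 0.375 (0.269 to 0.525) in the widest of 4 groups, which met the bound set beforehand. The narrowest group showed no deficit (0.924, 0.640 to 1.33). That bound cannot exclude lower power, because a single-copy X may have fewer reads at every peak width. A test added after that value was seen compared the narrowing of X and autosomal pairs. Fewer reads at the same peak width predicted equal narrowing, and otherwise less narrowing on the X was predicted. Neither outcome was met: X pairs narrowed more (difference in median log2 ratio -0.07, permutation p = 0.00831), by -0.13 at gene boundaries (p = 1e-05, the smallest possible) and by 0 elsewhere (p = 1). Width is no read count and the lists hold none, so lower power stays open. So does meiotic silencing of the X, a biological explanation that was not tested.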
